A study of Homo sapiens with 7 samples.

How the data were processed

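The series lists 7 libraries of THP-1 cells, each the single member of its group: 1 control m6A input library, 1 m6A capture library for each of 2 hairpins against YTHDF1, and 1 ribosome footprint and 1 mRNA library each of control cells and of cells with hairpin 1. The deposited table had 1 value column for each of 4 libraries and none for the other 3. Columns named for RNA were taken as the mRNA libraries by their names. Per the submitters' processing notes, reads were aligned with HISAT2 to mm10, a mouse build, and no version is given in the sources used here. Against this, all 9991 symbols of the deposited table were found with a human coding length in GENCODE v29 (GRCh38).

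Values deposited by the authors were taken as RPKM, reads scaled to length in kilobases and to library size. The length was taken as the coding length for footprints and as the transcript length for mRNA. The column headers give no unit, so this was tested: values were divided by the step of 1 read, given a gene length and a library total fitted to all genes. For footprints the length was the longest GENCODE coding length of each gene, and for mRNA that of the transcript that carries it. Whole read numbers, within 0.02 of a read, resulted for 97.6% of genes in footprints and 37.6% in mRNA. With the coding lengths (footprints) or transcript lengths (mRNA) shuffled between genes, these were 0.671% and 0.253% for genes with more than 20 reads. Library totals and read numbers come from this step, and 243 genes had no recovered footprint reads. The fitted totals were 3533752 and 2602074 footprint reads for knockdown and control, and 37021899 and 34299460 mRNA reads. The authors' 2 ratio columns are log2 of knockdown over control of the deposited values, and 6 mRNA ratio cells held spreadsheet error text. The authors' m6A call is TRUE or FALSE for each gene, and how it was made is not given in the sources used here.

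Changes were differences of log2(RPKM + 1), knockdown minus control, for genes with a mean of at least 1 RPKM in the libraries compared. The efficiency change was the footprint change minus the mRNA change, for genes past both filters. Counts of genes use a 2-fold limit on these changes, and no test between conditions was made because each group had 1 library. Ratios printed for single genes are ratios of RPKM without a pseudocount. Their 95% intervals are exact Clopper-Pearson intervals of the share of reads in the knockdown library, rescaled by the library totals. An efficiency interval divides the footprint bounds by the mRNA ratio and so leaves out mRNA counting error. Identifiers, positions and transcript lengths come from GENCODE v29, with the transcript of the longest coding sequence.

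A total of 19 gene lists was fixed before the data were examined, as were the groups, the comparisons, the alternative settings listed first below and the rule for named genes. A list's median change was placed among 10000 random lists of the same size matched on 10 bins of mean level, drawn with replacement, and was called outside below percentile 2.5 or above 97.5. Lists needed at least 3 genes, which left 17 with a percentile. About 5% of lists of unrelated genes are outside by chance, and for genes that vary together this share can be larger. The rule named YTHDF1, CCNE2 and MYC, then the 10 highest and 10 lowest genes of each comparison and of the authors' ratios, and up to 4 members of each list with the largest changes. Genes with at least 100 footprint reads were named in addition, after their values were seen.

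For the m6A call, a planned Fisher's exact test across genes is given as shares and an odds ratio, without p, since genes are not replicates. The m6A-called genes were also placed among 10000 random sets of genes matched on 10 bins of footprint reads, with and without 5 bins of transcript length. Intervals of correlations across genes come from 500 bootstrap draws of genes.

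The alternative settings fixed in advance were a pseudocount of 0.1, no filter, a filter of 5 RPKM, a 1.5-fold limit, the median change set to 0, and 20 bins for matching. Added after seeing the data were a minimum of 100 footprint reads, matching on transcript length, the reported targets without CCNE2, and the m6A readers without YTHDF1.

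The method was tested on simulated data with 9885 genes, 200 of them changed. Both totals and 100% of read numbers were recovered. Of 2-fold higher genes 86.9% and of 2-fold lower genes 68.7% were recovered, meaning that the interval of their ratio excluded 1. Above 100 reads 100% of each were recovered in this sense. How many passed the 2-fold limit used for counts of genes was not tested. Of unchanged genes 3.87% had an interval that excluded 1. Of 100 unchanged lists of 25 genes 1 was outside, and of 100 lists shifted by −0.3 all 100 were. Only footprints were simulated, with independent counting error and lists drawn at random, so genes that vary together between libraries were not covered. Smaller shifts were not tried, and among list medians only that of reported YTHDF1 targets in footprints (−0.51) was larger in size than 0.3.

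Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.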

Results

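Ribosome footprints and mRNA were measured in THP-1 cells, a human monocytic line derived from acute myeloid leukaemia (AML), with and without knockdown of YTHDF1. YTHDF1 is a cytoplasmic protein that binds N6-methyladenosine (m6A), a methyl mark on adenosines of mRNA, and it is known to affect the translation of transcripts it binds. The series addresses the role of this reader in AML and names translation as the process of interest. Knockdown used short hairpin RNA (shRNA), which lowers a target mRNA by RNA interference. Ribosome profiling sequences the stretches of mRNA that ribosomes protect from nuclease, so footprints of a gene count ribosomes on its coding sequence. The table used here held 1 footprint library and 1 mRNA library of control cells, and 1 of each from cells with hairpin 1 of the 2 hairpins against YTHDF1. Another 3 libraries of m6A experiments had no values of their own and were not used here. An m6A call, yes or no, was given for each gene, and 6114 of the 9991 genes (61.2%) were called. The library totals behind the values were 3533752 footprint reads for the knockdown and 2602074 for the control, and 37021899 and 34299460 mRNA reads. A gene had a median of 149 footprint reads over both libraries. There were no replicates, so every difference given is between 2 single libraries, and intervals cover counting error only.

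RPKM is a read density scaled to library size and length, taken as the coding length for footprints and the transcript length for mRNA. On log2(RPKM + 1), YTHDF1 itself had the lowest footprint change of the 9549 genes compared. Its footprints were 70.6 RPKM in the control library (308 reads) and 12.5 in the knockdown library (74 reads), a ratio of 0.177 (95% interval 0.135 to 0.229). Its mRNA was 20.9 RPKM in the control and 9.75 in the knockdown, a ratio of 0.467. The gene (ENSG00000149658.17) lies on chromosome 20 of GRCh38 from 63195429 to 63216234, on the minus strand, and carried an m6A call.

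CCNE2, which encodes cyclin E2, a partner of CDK2 at the start of DNA synthesis, had fewer footprints at a like mRNA level. Footprints were 93.9 RPKM in the control and 62.3 in the knockdown, a ratio of 0.664 (0.561 to 0.786), while mRNA was 20.5 and 20.3 RPKM, a ratio of 0.989 (0.935 to 1.05). The footprint to mRNA ratio of CCNE2, its translation efficiency, was therefore 0.671 times the control value (0.567 to 0.795, with footprint counting error alone). MYC, a transcription factor that drives growth in many cancers, was lower in both assays by a like factor. MYC footprints were 235 and 200 RPKM (ratio 0.852, 0.776 to 0.936), mRNA was 37.3 and 31.9 RPKM (ratio 0.855), and the efficiency ratio was 0.997 (0.907 to 1.09). CCNE2 spans 94879770 to 94896678 on the minus strand of chromosome 8, and MYC 127735434 to 127741434 on the plus strand of the same chromosome.

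**Figure D1:**
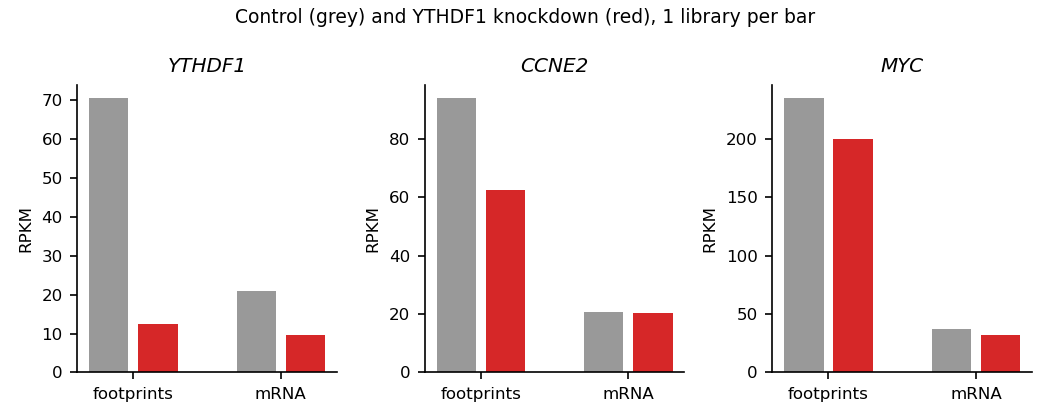
Footprint and mRNA levels in RPKM of YTHDF1, CCNE2 and MYC, where each bar is 1 library, grey for control and red for knockdown. YTHDF1 was lower in both assays (footprints 70.6 and 12.5, mRNA 20.9 and 9.75), and CCNE2 had footprints of 93.9 and 62.3 beside mRNA of 20.5 and 20.3.

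The mRNA comparison asks which transcripts differed in abundance between knockdown and control cells. VIM, which encodes the intermediate filament vimentin, was 32.5 RPKM in the control and 88.6 in the knockdown, and its footprints were 212 and 433 RPKM (ratio 2.04, 1.87 to 2.21). Of the fixed myeloid differentiation markers, 19 of 29 were higher and 10 lower, with 3 at least 1.5-fold higher and 2 at least 1.5-fold lower. Among them VCAN, a matrix proteoglycan made by monocytes, was 6.53 and 13.7 RPKM in mRNA, with a footprint ratio of 1.94 (1.78 to 2.11), and the scavenger receptor gene CD36 was 6.61 and 12.2 RPKM. The calgranulin genes S100A8 and S100A9, abundant in neutrophils and early monocytes, were lower, at 6.54 and 3.27 RPKM and at 24.0 and 14.4 RPKM. Of 9433 genes, 13 were at least 2-fold higher in mRNA and 12 at least 2-fold lower, and with a pseudocount of 0.1 in place of 1 these were 32 and 38.

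The most elevated mRNAs by log2 change were NCAM1, a neural adhesion molecule also seen on some leukaemias (3.33 and 15.8 RPKM), C4orf48 (11.1 and 31.8), VIM and the heat shock gene HSPA6 (3.17 and 9.67). HLA-F, FCER2, SNURF, SECTM1, TULP3 and CREB3L1 followed, with log2 changes from 1.13 for CREB3L1 to 1.32 for HLA-F. Of these, VIM and TULP3 (5.52, 1.28 to 49.8) had footprint ratios above 1, and the others lay below 1. SECTM1 had 0.283 (0.0791 to 0.847) and SNURF 0.245 (0.0427 to 0.984). NCAM1 had 0.736 (0.137 to 3.95, from 4 reads in each library), C4orf48 0.757 (0.462 to 1.24), HSPA6 0.644 (0.199 to 2.03) and HLA-F 0.491 (0.174 to 1.31), and FCER2 and CREB3L1 had 0.915 and 0.920, all with intervals that included 1. HLA-F has close paralogs and SNURF shares transcripts with SNRPN, so the origin of their reads is uncertain. At the low end stood LBH (2.34 and 0.278 RPKM), HIVEP2 (9.20 and 3.10), the cathelicidin gene CAMP (1.88 and 0.181) and the potassium channel gene KCNA3 (2.31 and 0.404). FAM163A, BEX1, the glutamine transporter gene SLC38A1, the transcriptional regulator gene AFF3, IFT43 and HSH2D had log2 changes from −1.22 for FAM163A to −1.12 for HSH2D. SLC38A1 mRNA was 29.2 and 12.4 RPKM, whereas its footprints were 237 and 201 RPKM (ratio 0.850, 0.778 to 0.929).

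Among gene lists, markers of myeloid differentiation had a median mRNA change of 0.19 (log2), and this median stood at percentile 99.9 of random lists matched on level. Glycolytic enzymes had a median of 0.22 (percentile 99.8), with 15 of 16 members higher, among them PGAM1 at 86.0 and 117 RPKM and PFKP at 30.3 and 40.7 RPKM. Oncogenes and stem cell genes of AML had a median of −0.16 (percentile 0.36), with 20 of 26 members lower. In that list the survival gene BCL2 was 40.7 and 26.4 RPKM, the receptor gene KIT was 3.95 and 2.25, and IDH2 and IL3RA were the highest members, with ratios of 1.12 and 1.18. Genes of DNA replication had a median of −0.12 (percentile 1.52), with 22 of 29 lower, among them POLA1 (ratio 0.702) and ORC1 (ratio 0.732). The m6A readers had a median of −0.19 (percentile 1.42), and without YTHDF1 it was −0.18 (percentile 1.63). YTHDF3 mRNA had a ratio of 0.839 and YTHDF2 mRNA a ratio of 1.16. Interferon-stimulated genes had a median of 0.11 (percentile 99.1), with 13 of 24 members higher and 11 lower. ISG15 was 24.4 and 41.3 RPKM, whereas OAS2 and IFIT2 had ratios of 0.712 and 0.776, and the list's percentile was 94.6 among lists matched on transcript length as well. Cytosolic ribosomal protein genes had a median of −0.0027, below matched lists at percentile 0.98, and it became 0.025 once the median of all genes was set to 0. In total 7 of 16 lists lay outside the central 95% of random lists in mRNA, and 6 did when random lists were also matched on transcript length. The other 9 had medians between −0.05 for m6A writers and erasers and 0.12 for mitochondrially encoded proteins.

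The footprint comparison asks which genes had more or fewer ribosomes on their coding sequence. Below YTHDF1, the gene with the most reads among the low ones was RPS27, which encodes a protein of the small ribosomal subunit. RPS27 footprints were 64151 RPKM in the control (42065 reads) and 19956 in the knockdown (17771 reads), a ratio of 0.311 (0.306 to 0.317), beside an mRNA ratio of 1.01. RPS27 has many processed pseudogenes and the paralog RPS27L, so the origin of these reads is uncertain. The transcription factor gene EBF3 and the adaptor gene HSH2D were lower in both assays, with footprint ratios of 0.184 for each (0.0733 to 0.408) and mRNA ratios of 0.498 and 0.417. C12orf73, TTC9, RAB3A, SNURF, ISCA1 and HILPDA made up the rest of the lowest 10, each with 15 or fewer control reads.

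At the high end of footprints, the stress gene NUPR1 was 2.56 RPKM in the control (2 reads) and 21.7 in the knockdown (23 reads), a ratio of 8.47 (2.09 to 74.1). UFM1, a ubiquitin-like modifier, had 5 and 39 reads (ratio 5.74, 2.26 to 18.7). KCNMB1, a subunit of a calcium-activated potassium channel, had 26 and 139 reads (ratio 3.94, 2.58 to 6.24). C19orf12, FAM89B, RHOB, NPY, ULBP3, AP4M1 and CUEDC1 completed the highest 10, each with 6 or fewer control reads. Of 9549 genes, 170 were at least 2-fold higher in footprints and 136 at least 2-fold lower, a balance that turned to 143 and 156 with the median change of all genes (0.04) set to 0. With at least 100 footprint reads, a limit chosen after the data were examined, 21 and 13 were. With at least 1000 footprint reads 3 and 5 of 994 genes were. The 95% interval of the footprint ratio lay above 1 for 1487 genes and below 1 for 1047 of 9317, or 27.2%, against 3.87% of unchanged genes in data simulated with counting error alone.

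By list, genes reported as YTHDF1 targets in other cell systems, recalled from general knowledge, had a median footprint change of −0.51 (percentile 0.085), with 5 of 7 lower. TRAF6, a ubiquitin ligase of inflammatory signalling, had 29.9 and 16.8 RPKM in footprints (ratio 0.561, 0.424 to 0.741) at an mRNA ratio of 1.02. The autophagy gene ATG14 had a ratio of 0.618 (0.352 to 1.07), USP14 had 1.08 (0.885 to 1.32) and the Wnt receptor gene FZD7 had 2.36 (0.825 to 8.22). CCNE2 was put in this list from knowledge of this study, so it is not independent evidence of the list's direction. Without CCNE2 the median was −0.32, at percentile 2.86, inside the central 95%. DNA replication genes had a median footprint change of −0.09 (percentile 1.17), with 18 of 29 lower, among them RFC5 (ratio 0.699, 0.595 to 0.821) and GINS3 (0.721, 0.540 to 0.964). The other 15 lists lay inside, with medians from −0.07 for m6A readers to 0.26 for mitochondrially encoded proteins.

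Within the other lists, single members had footprint ratios whose interval excluded 1. GSPT1, the translation termination factor eRF3a, had a ratio of 0.538 (0.463 to 0.623), and the 60S subunit factor gene EIF6 had 0.617 (0.562 to 0.677). The subunit gene COX5B of cytochrome oxidase had 0.567 (0.517 to 0.621), and the mitotic gene CENPF 0.649 (0.610 to 0.691). Among m6A enzymes METTL14 had 0.589 (0.412 to 0.838, from 75 and 60 reads) and its partner METTL3 had 1.49 (1.14 to 1.97). The survival gene XIAP had 0.586 (0.365 to 0.934, from 44 and 35 reads) and CYCS, which encodes cytochrome c, 1.44 (1.29 to 1.62). The retinoic acid inducible sensor gene DDX58 had 0.320 (0.136 to 0.699, from 23 and 10 reads) and ISG15 had 1.66 (1.22 to 2.28). AML genes outside the central 95% only when transcript length was matched too (median 0.18, percentile 98.1 in place of 95.5) included MCL1 (1.61, 1.41 to 1.83) and KIT (0.418, 0.285 to 0.608). The G1/S inhibitor gene CDKN1B had 1.76 (1.22 to 2.58).

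**Figure D2:**
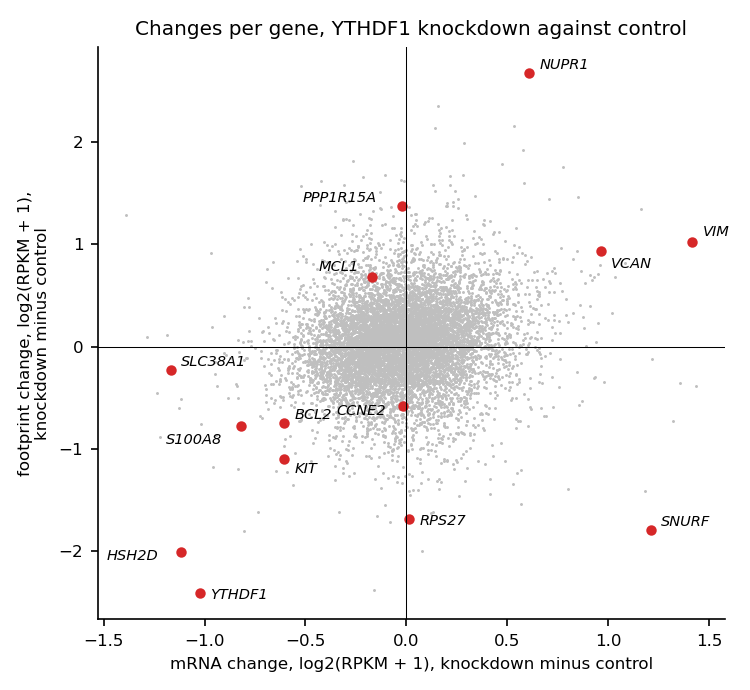
Change in footprints (y axis) against change in mRNA (x axis), both as log2(RPKM + 1) of the knockdown library minus control, with each point 1 of 9203 genes and some of the named genes in red. YTHDF1 lies at −1.02 in mRNA and −2.41 in footprints, VIM at 1.42 and 1.02, and RPS27 at 0.01 and −1.68.

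Translation efficiency, the footprint change minus the mRNA change, addresses the question of the series most directly. CCL5, NRGN and VAPA, which have at least 100 footprint reads and were named after their values were seen, had lower efficiency in the knockdown library. The chemokine gene CCL5 had footprints of 2355 and 862 RPKM and mRNA of 146 and 148 RPKM, an efficiency ratio of 0.361 (0.332 to 0.393). VAPA, which tethers the endoplasmic reticulum to other membranes, had an efficiency ratio of 0.370 (0.349 to 0.393) beside an mRNA ratio of 1.18, and the calmodulin-binding gene NRGN had 0.405 (0.376 to 0.436) beside 1.06. RPS27 had an efficiency ratio of 0.308 (0.303 to 0.314) at an mRNA ratio of 1.01. The glycolytic gene ALDOA had 0.459 (0.449 to 0.469) with higher mRNA (ratio 1.29), and YTHDF1 had 0.379 (0.290 to 0.490) with lower mRNA (ratio 0.467).

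Higher efficiency was seen for PPP1R15A, a phosphatase subunit that ends the integrated stress response, whose mRNA was 57.7 and 56.9 RPKM while its footprints were 4.37 and 12.9 RPKM. Its efficiency ratio was 2.99 (1.88 to 4.95). The survival gene MCL1 had an efficiency ratio of 1.81 (1.59 to 2.06), its relative BCL2L1 had 2.10 (1.19 to 3.84), and CDK2 had 1.81 (1.55 to 2.12) beside an mRNA ratio of 0.607. SLC38A1 and BEX1, both among the lowest mRNAs, had efficiency ratios of 1.99 (1.82 to 2.18) and 2.5 (1.94 to 3.24). BEX1 footprints had a ratio of 1.08 (0.837 to 1.40). Efficiency subtracts the mRNA change, so mRNA differences and mRNA error enter it with opposite sign. Across 9203 genes Spearman's rho of efficiency and mRNA change was −0.44 (bootstrap interval −0.45 to −0.42). The translation factor genes EIF6 and EIF1 had ratios of 0.482 (0.439 to 0.529) and 0.533 (0.505 to 0.562). RPL36AL, a ribosomal protein gene, had 0.526 (0.490 to 0.565).

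By the fixed rule, the lowest efficiency changes were those of SNURF (−3.0), SECTM1 (−2.59), C12orf73, ICAM2, YPEL3, RAB3A, HLA-F, FBXW9, ENDOG and C4orf48 (−1.82). The highest were those of LBH (2.67), UFM1 (2.19), RBM38, AP4M1, NUPR1, FAM104B, RHOB, MDK, NUMBL and CHCHD6 (1.87). FBXW9 had the most control footprint reads of these, 60, and LBH, RBM38 and MDK had 1. SNURF, SECTM1, HLA-F and C4orf48 were also among the 10 highest mRNAs, and LBH was among the 10 lowest. Of 9203 genes, 207 had at least 2-fold higher efficiency and 161 at least 2-fold lower, and with the median change of all genes (0.07) set to 0 the split turned to 164 and 197. With at least 100 footprint reads the counts were 45 and 27, and with at least 1000 they were 2 and 10 of 993 genes.

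None of the 16 lists lay outside the central 95% of random lists in efficiency. The AML oncogenes and stem cell genes had a median of 0.19 (percentile 96.4), with 21 of 26 members higher. Cytosolic ribosomal protein genes had a median of 0.10 (percentile 96.7), which lay at 97.6 when random lists were also matched on transcript length and at 98.1 with a minimum of 5 RPKM, outside the central 95% in both. Reported YTHDF1 targets had a median of −0.18 (percentile 8.72), which was −0.11 without CCNE2 (percentile 17.3) and −0.03 with a minimum of 5 RPKM, where 3 members were left (percentile 34.4). Glycolysis genes had a median of −0.09 (percentile 11.8), and between −0.16 and −0.03 over the settings tried. Of apoptosis regulators 13 of 18 were higher (median 0.18, percentile 81.9), and of DNA replication genes 19 of 29 (median 0.07, percentile 61.9). The m6A readers (percentile 17.5), m6A writers and erasers (34.3), G1/S genes (48.3), G2/M genes (40.0), myeloid markers (15.5) and translation factors (51.9) lay inside. So did mitochondrially encoded proteins (58.8), nuclear oxidative phosphorylation genes (33.3), integrated stress response genes (47.1) and interferon-stimulated genes (19.0). Of 23 markers of other cell types, 5 were in the table and 4 could be compared in footprints (percentile 58.0). None of 20 replication-dependent histone genes or 11 noncoding RNAs was in the table.

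**Figure D3:**
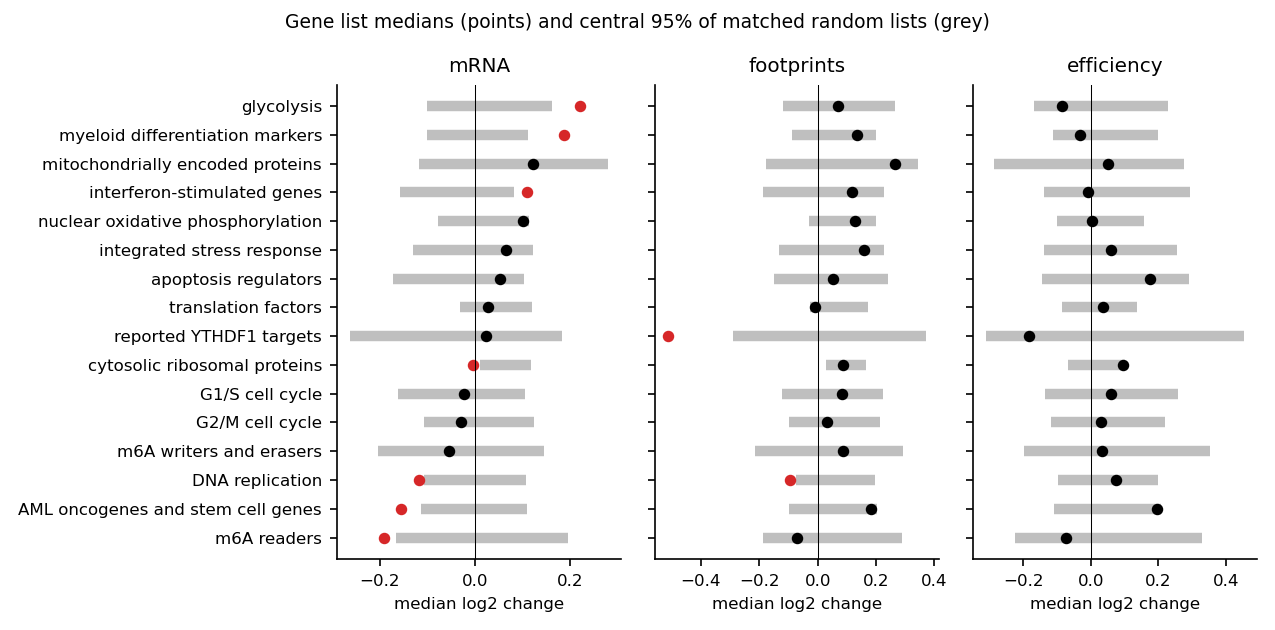
Median log2 change of each gene list (points, red where outside) with the central 95% of 10000 random lists matched on level (grey bars), from left to right for mRNA, footprints and efficiency, with 1 library per condition. In mRNA 7 of 16 lists lay outside, glycolysis the highest at 0.22, and in efficiency none of 16 did.

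The m6A call allows a comparison of called genes with other genes. How the call was made is not given, so genes without it are not known to lack the mark. Genes with an m6A call had a median efficiency change of 0.0752 and genes without it 0.0711, a difference of 0.0041 on the log2 scale that was −0.0033 with a pseudocount of 0.1. Among random sets of genes matched on footprint reads the m6A-called median stood at percentile 79.2, and with transcript length matched too at 21.6. At least 2-fold lower efficiency was found for 81 of 5886 m6A-called genes (1.38%) and for 80 of 3317 others (2.41%), an odds ratio of 0.565. Of genes named above, CCL5, VAPA and NRGN were at least 2-fold lower and carried the call, and EIF6 was and did not. Among genes lower by less than 2-fold, TRAF6 and CCNE2 carried it, and KIT and METTL14 did not. These genes were picked and do not measure a share. At least 2-fold higher efficiency was found for 98 m6A-called genes (1.66%) and 109 others (3.29%). With at least 100 footprint reads the odds ratio for lower efficiency was 1.24, from 27 genes with lower efficiency. Neither odds ratio is given with an interval. The 0.565 rests on 161 genes with lower efficiency, whereas 27 genes are few and leave the direction at that read limit open. Genes with the call had more footprint reads, with a median of 209 against 120.

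**Figure D4:**
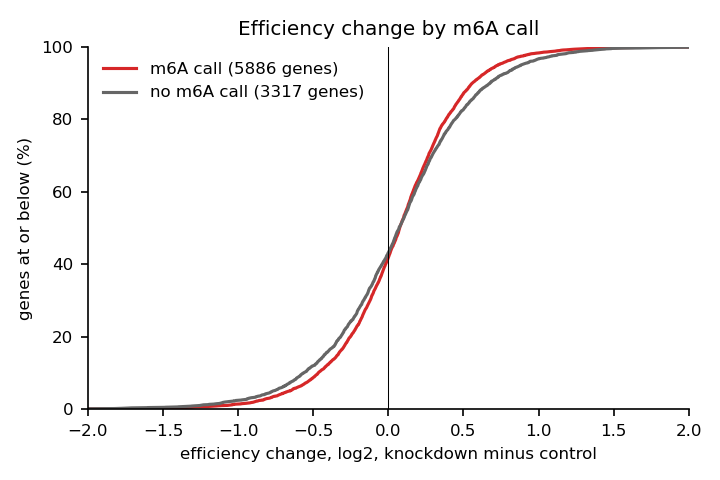
Cumulative share of genes in percent (y axis) by log2 efficiency change, knockdown library minus control (x axis), for 5886 genes with an m6A call (red) and 3317 without (grey). The curves cross near the medians of 0.0752 and 0.0711, and the m6A-called genes are spread less widely.

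Longer transcripts were lower in mRNA. The quintile of genes with the shortest transcripts (207 to 1750 nt) had a median mRNA change of 0.11, and the quintile with the longest (5270 to 34526 nt) had −0.17. Across 9203 genes, which are not independent replicates, Spearman's rho of mRNA change with transcript length was −0.38 (bootstrap interval −0.40 to −0.36), 1 of 15 relations across genes computed. Median footprint changes went from 0.10 in the shortest to −0.02 in the longest quintile, and median efficiency changes from −0.01 to 0.16. Of the gene lists, cytosolic ribosomal protein genes were short (median transcript 908.5 nt), whereas the reported YTHDF1 targets were long (4627 nt).

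**Figure D5:**
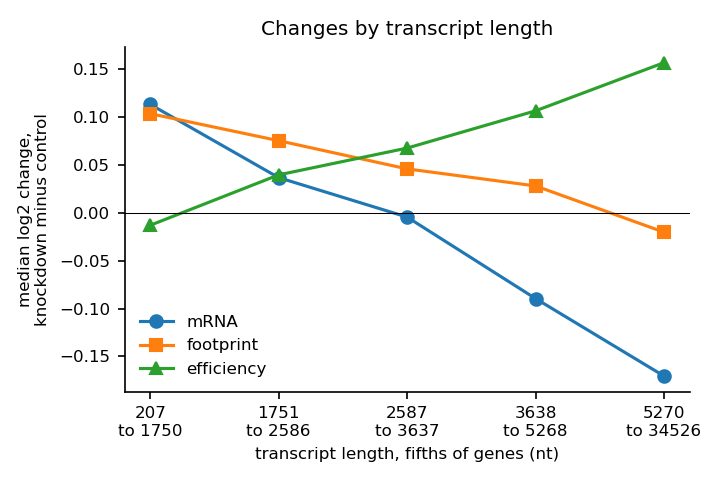
Median log2 change, knockdown library minus control (y axis), of mRNA, footprints and efficiency in quintiles of 9203 genes by transcript length in nt (x axis), with each point the median of a quintile. The mRNA medians run from 0.11 down to −0.17 and the efficiency medians from −0.01 up to 0.16.

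The authors' own table gave log2 ratios without a pseudocount. By these, YTHDF1 was at −2.5 in footprints and −1.10 in mRNA, CCNE2 at −0.59 and −0.02, and MYC at −0.23 in both. At least 2-fold higher deposited ratios were found for 438 genes in footprints and 76 in mRNA, and at least 2-fold lower ones for 390 and 117. Those counts used no filter, whereas the extremes were sought among protein-coding genes with a mean of at least 1 RPKM. Among these the lowest footprint ratio was that of MAMDC2 (−3.25, from 14 and 2 reads). The highest was that of C19orf12 (3.31, from 2 and 27 reads). In mRNA, within the same limits, the lowest was CAMP (−3.37) and the highest NCAM1 (2.24).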

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

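The limit of 100 footprint reads, matching on transcript length and the lists without CCNE2 or YTHDF1 were chosen after seeing the data. Unless stated otherwise, the cause of a difference between settings was not tested. With a pseudocount of 0.1, genes at least 2-fold higher and lower numbered 314 and 262 in footprints, 32 and 38 in mRNA, and 373 and 265 in efficiency, the median efficiency change of m6A-called minus other genes was −0.0033, and the YTHDF1 mRNA change was −1.09. With a filter of 5 RPKM, which leaves fewer genes, there were 92 and 62 in footprints, 7 lower in mRNA, and 80 and 65 in efficiency, the m6A difference was 0.019, the odds ratio of an m6A call among genes with lower efficiency was 0.788, and 1 list, the cytosolic ribosomal proteins, lay outside in efficiency. With at least 100 footprint reads, again fewer genes, there were 21 and 13 in footprints and 45 and 27 in efficiency, the m6A difference was 0.020, the odds ratio was 1.24, and 1 list lay outside in efficiency. Matching on level and transcript length also put 1 list outside in efficiency. A limit of 1.5-fold, wider by construction, gave 818 and 627 genes in footprints, 144 and 130 in mRNA, and 970 and 678 in efficiency, and by the authors' ratios 1171 and 1006 in footprints and 309 and 486 in mRNA. With the median log2 change set to 0, the YTHDF1 mRNA change was −0.998 and the median mRNA change of cytosolic ribosomal proteins turned to 0.025, since the shift of all genes exceeds its value.

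Of the alternative medians of gene lists, 320 stayed close to the main value, 10 moved and 1 changed sign, and for named genes 418 stayed close and 112 moved. Alternatives for a comparison of the hairpins by m6A were not run, because no m6A column belonged to a library. Leaving out a replicate was not possible. No paired analysis was possible because each group holds 1 library. Depth limits footprints most, with totals of 3533752 and 2602074 reads: 927 genes had under 20 footprint reads over both libraries.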

Other observations

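The tests with matching on transcript length, the separate tests of higher and lower efficiency, the trend of footprints with transcript length and the removal of counting variance were chosen only after the result was seen. In control cells, genes with an m6A call had more mRNA and a lower footprint to mRNA ratio, both as densities in RPKM. Their median mRNA was 15.8 RPKM and that of other genes 7.43, and the median log2 efficiency was 0.39 against 0.85. Their median transcript length was 3294.5 nt against 2687 nt, and these medians were matched on neither level nor length.

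Genes of the respiratory chain and mitochondrial translation products also differed in single members. The mitochondrially encoded MT-ND4L had 37 and 98 footprint reads in control and knockdown (ratio 1.95, 1.32 to 2.93). MT-ATP6 had 394 and 674 (1.26, 1.11 to 1.43). MT-ATP8, whose reading frame overlaps that of MT-ATP6, had a ratio of 0.917 (0.899 to 0.935). Its control footprints were 33516 RPKM beside 223 for MT-ATP6, at control mRNA of 8814 and 7404 RPKM. The origin of the MT-ATP8 footprint reads is therefore uncertain. Nuclear COX7C was 243 and 470 RPKM in mRNA and 1997 and 3275 RPKM in footprints, and COX7A2 footprints were 2168 and 3458 RPKM beside mRNA of 75.9 and 81.6. RPS27L, a paralog of RPS27 named after its values were seen, had 147 and 470 footprint reads (2.35, 1.95 to 2.85), opposite in direction to RPS27 with 42065 and 17771. The lysosomal protease gene CTSB, also named after its values were seen, had 246 and 748 footprint reads (2.24, 1.94 to 2.60) beside an mRNA ratio of 1.47.

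Genes with an m6A call were rarer among genes with a 2-fold efficiency difference, at 3.04% of those with recovered reads, where random sets matched on footprint reads had 3.09% to 3.70% (percentile 1.145). This rests on higher efficiency, at 1.67% (percentile 1.77), just below the random range of 1.69% to 2.16%. Matching was by bins of reads, so differences in reads within a bin could remain. The SD of log2 footprint ratios was 1.17 for genes under 20 reads and 0.77 at 20 to 49. The test therefore cannot decide whether fewer reads behind the other genes are the sole source. For lower efficiency, at 1.37%, the share stood at percentile 16.25, so read numbers alone may account for it. With at least 100 reads the odds ratio was 1.24, from 27 genes with lower efficiency. Reads together with transcript length may account for the whole pattern, because with both matched the percentile was 13.495. Loss of YTHDF1 as a biological explanation stays untested with 1 library per group.

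Lower mRNA of longer transcripts was found also among genes without an m6A call (rho −0.2497, interval −0.280 to −0.216), which argues against the m6A call as its whole source. The trend was stronger among m6A-called genes (rho −0.46, −0.48 to −0.44), so a part that goes with the call stays open. Weakly expressed genes are not its source either, since rho was −0.439679 at 10 RPKM and more. Uneven recovery of RNA by length in the mRNA libraries stays open and cannot be told apart from a difference in the cells, because footprints of genes with at least 100 reads had rho −0.153716 (−0.178 to −0.130), between the values set as limits. Knockdown of YTHDF1 is confounded with the library and stays untested.

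Differences in mRNA were weakly carried into footprints, with Pearson's r of 0.142 (0.117 to 0.166) across 9203 genes, which are not independent replicates. Holding transcript length constant did not raise the relation. Spearman's rho was 0.148 and, given length, 0.116309 (0.0954 to 0.139). Among genes with at least 1000 footprint reads and counting variance taken out, r given length was 0.240813 (0.167 to 0.311). Both changes fell with length, so the shared trend adds to the relation and taking it out lowers the value. The limit of 0.5 for naming the trend as the source was therefore out of reach. The values show only that the trend did not hide a stronger relation. Counting noise cannot be told apart as a source over all genes. Among genes with at least 1000 footprint reads r was 0.275108 (0.216 to 0.337), an interval that crosses the limit of 0.3 set for excluding such noise. For those genes footprint counting error was a small part of the spread, with a variance of 0.00449 beside 0.0951 for log2 footprint ratios. Being this small, it is argued against as their main source. With it taken out r was 0.281906 (0.215 to 0.353). That value alone decides nothing, because its limit of 0.5 was set after the result was seen and was out of reach. Changes in translation, or differences between library preparations, could both remain, and neither was tested.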
